A study of Mus musculus with 96 samples.

How the data were processed

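Counts were analysed from 96 samples of mouse bone marrow-derived macrophages grown for 7 days in L929-conditioned medium, with H3K4me1 ChIP-seq in 34, ATAC-seq in 36 and RNA-seq in 19; the 7 input samples have no column in the tables used here. Per the labels' protocols the stimuli were TNF at 10 ng/ml, Pam3CSK4 at 100 ng/ml, LPS at 100 ng/ml, CpG at 1 uM (10 uM in the sample labels) and poly(I:C) at 50 ug/ml (50 uM in the sample labels), and the WT and dKO samples were taken at 8 h. The genotype entry contradicts the title in 36 of the 75 samples of the Ctrl, IkBaKO, WT ATAC and IkBakB groups; titles and column names were followed. Groups had 2 libraries, except dKO (1 per stimulus) and Ctrl RNA at 1 h (1). Replicate numbers are 1 and 3 for the Ctrl and IkBaKO ATAC, 2 and 4 for their H3K4me1, and 1 and 2 elsewhere. Whether replicates came from separate cultures is not given in the sources used here, so the p-values measure only the spread between these libraries, part of which may be technical.

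All tables hold raw counts deposited by the authors, checked as whole numbers with totals that differ between libraries. Per the submitters' processing notes, MACS2 2.1.0, Bowtie2, SAMtools, Picard, deepTools, featureCounts and Subread were used for chromatin and STAR, featureCounts and Subread for RNA, with build mm10; versions of the others, their settings, and which tool made which table are not given in the sources used here. The tables hold 80206 WT and 80194 dKO H3K4me1 regions (median width 1920 bp), 100457 H3K4me1 regions for Ctrl and IkBaKO (1498 bp), 101701 ATAC windows of 200 bp for Ctrl and IkBaKO, 71398 ATAC regions for WT and IkBakB (396 bp) and 44099 genes, 43536 of them with a symbol. The ATAC windows overlap: 65041 start 100 bp after the one before, and merging leaves 35091 sites, so neighbouring windows are not independent. Library totals were 8.58 to 15.8 in units of 1e6 counts (WT H3K4me1), 4.69 to 13.6 (dKO), 8.45 to 21.1 (Ctrl and IkBaKO H3K4me1), 1.53 to 5.09 (their ATAC), 0.770 to 1.93 (WT and IkBakB ATAC) and 4.51 to 9.20 (RNA).

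Each table was fitted in R 4.3.3 with edgeR 4.0.16: groups as a factor without a block, filterByExpr by group (78989, 100055, 101681, 50505 and 11945 rows tested in the WT, Ctrl and IkBaKO H3K4me1, the 2 ATAC and the RNA tables), TMM factors and the quasi-likelihood F test, with the Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. The standard error is the log2 fold change divided by the square root of F. Group means are CPM, library-scaled counts on TMM-scaled library sizes. Differences in response are interaction contrasts, the change in one genotype minus the change in the other. Where a group had no counts its fold is not given. The dKO libraries, without replicates, were not tested by region: the median log2 change over unstimulated cells (log2 CPM with a prior count of 2) at classes of WT-induced regions was compared with 10000 random lists matched on mean signal in 20 bins. Gene lists were tested with limma 3.58.1 (camera with a preset correlation of 0.01 and with an estimated one; fry beside it), adjusted over the lists of each comparison for RNA and over the tests of one question for region sets. Overlaps used GenomicRanges 1.54.1. Classes of WT-induced regions were tested in the Ctrl and IkBaKO data and in the WT and IkBakB ATAC data the same way, adjusted over 104 tests.

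The lists were written by hand and hold genotype genes, NFkB pathway and feedback, inflammatory cytokines, chemokines, interferon-stimulated genes, immediate early and AP-1 genes, antimicrobial and effector genes, antigen presentation, alternative activation, macrophage identity, glycolysis and hypoxia, cholesterol and lipid synthesis, cell cycle, survival and apoptosis, and markers of neutrophils, dendritic cells, lymphocytes, stromal cells, erythroid and mast cells and osteoclasts. A list of mitochondrial transcripts was not used here. Regions take the name of the nearest gene span within 100 kb, or the nearest beyond it, since the annotation gives gene spans. A panel of 30 genes was followed with every region within 50 kb. Items were named by a rule set before the data were examined: for RNA, the genes of the genotypes, up to 10 higher and 10 lower by size of change in each comparison among those past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap, and the 4 smallest p of each list; for regions, 5 higher and 5 lower by the same rule and the region with the smallest p near each panel gene. Genes known only by a clone or locus number were counted and not named. The text prefers named items that kept their call with each library left out; that preference, and Mid1, were chosen after the values were seen.

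The comparisons, the threshold and the alternatives were set before the data were examined, apart from the H3K4me1 and ATAC genotype comparisons at later times, 24 h against 8 h, the RNA response differences at 3 h and 8 h, the tests of WT classes in the other data, and their alternatives, which were added afterwards. Alternatives were DESeq2 1.42.0 size factors in edgeR, scaling to total counts alone, no filter on low counts, the replicate number as a block, the DESeq2 Wald test, and leaving out each library in turn, where the remaining library of a group is assumed to vary like the other groups; for region sets also a prior count of 0.5, an overlap of at least 50% of a region, WT-induced sets of at least 2-fold, and nearest genes within 25 kb. A motif test was set out as well and not run, because it needs the mm10 sequence, which was not used here.

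Recovery was tested on simulated data, 100 rows changed per fold size among libraries simulated with the estimated spread. Unchanged rows called in the same runs numbered 7 for WT LPS, 14 for IkBaKO H3K4me1 at 8 h and 7 for its response difference. They numbered 2 for IkBakB ATAC at 8 h, 3 for RNA at wash and 0 for the other comparisons simulated. The share of 1.5-fold and 2-fold changes found was 11% and 49% for WT LPS, 25% and 67% for IkBaKO H3K4me1 at 8 h, 4% and 39% for its response difference, 0% and 1% for IkBaKO ATAC at 8 h, 1% and 15% for IkBakB ATAC at 8 h, 0% for either ATAC response difference, 22% and 72% for RNA at wash, and 1% and 12% for the RNA response difference. Replicates were checked for copies: the chi-square per row between them was 1.17 to 2.52 for chromatin and 9.20 to 16.1 for RNA, and no library repeats another.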

Results

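The libraries came from mouse bone marrow-derived macrophages. H3K4me1, a histone mark of enhancers, was profiled in WT cells left unstimulated or given TNF, Pam3CSK4 (called Pam3CSK here), CpG, LPS or poly(I:C) (pIC). It was also profiled in dKO cells, which per the labels lack Irf3 and Ifnar. Per the labels Ctrl cells lacked Tnf, Rel and Nfkbie, and IkBaKO cells lacked Nfkbia as well, the gene of the NFκB inhibitor IκBα. Both were given TNF and profiled by H3K4me1 ChIP-seq, ATAC-seq and RNA-seq. IkBakB cells, homozygous for a kB allele of Nfkbia per the labels, were compared with WT by ATAC-seq alone. Log2 fold changes are given ± SE and library-scaled counts (CPM) as mean ± SD, with n = 2 libraries per group unless stated. Adjusted p comes from edgeR's quasi-likelihood test after the Benjamini-Hochberg step. Regions are named by the nearest gene, which does not make that gene their target.

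LPS raised H3K4me1 near Il6, Nos2, Tnfaip3 and Fpr1 in WT macrophages. A region 14796 bp from Il6 (chromosome 5, 29996729 to 29998317) had 5.64 ± 1.01 against 0.520 ± 0.0590 CPM in unstimulated cells (log2 3.40 ± 0.36, adjusted p = 1.3e-05). Regions at Nos2 (chromosome 11, 78871960 to 78879412; log2 2.91 ± 0.20, 30.1 against 3.91 CPM), Tnfaip3 (log2 3.44 ± 0.36) and Fpr1 (log2 3.72 ± 0.41) rose as well. Larger changes lay near Ubr4 (chromosome 4, 139440942 to 139443446; log2 4.35 ± 0.38, 14.7 against 0.809 CPM) and Acsl1 (log2 4.22 ± 0.52). Regions at Irf7 (log2 1.77 ± 0.26), Nfkbiz (1.53 ± 0.18), Saa3 (1.2 ± 0.12), Cxcl10 (1.12 ± 0.11, 68.7 against 31.6 CPM) and Gbp2 (1.16 ± 0.14) carried the mark before LPS and gained less. A region at Il15 (chromosome 8, 82397741 to 82400636) fell by 1.57 ± 0.20 on the log2 scale. Of 78989 tested regions 5854 higher and 759 lower passed the threshold (10370 and 5590 with the replicate number as a block). Of 29 panel genes with a tested region within 50 kb, 20 had one that rose. Leaving out 1 library brought the LPS count from 6613 to 2691 (without unstimulated replicate 2) to 4979. In every such fit 23 of 30 listed regions kept their call, those named here among them.

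The response to pIC included regions near Inhbb (chromosome 1, 119437731 to 119439274; log2 4.18 ± 0.39, 5.72 ± 1.15 against 0.295 ± 0.0792 CPM, adjusted p = 1.7e-05), Rnf225 (log2 3.98 ± 0.49) and Gpd2 (log2 3.94 ± 0.54). As for LPS, it also included Ubr4 (log2 3.89 ± 0.39) and Fpr1 (log2 3.71 ± 0.40). At Nos2 a broad region (chromosome 11, 78882094 to 78890911) rose from 15.5 to 46.7 CPM (log2 1.60 ± 0.12). Smaller gains lay at Irf1 (1.18 ± 0.19), Nfkbiz (1.06 ± 0.19), Gbp2 (1.00 ± 0.14) and Cxcl10 (0.89 ± 0.11). The Il15 region fell here as well (log2 -2.07 ± 0.21, 4.00 against 16.9 CPM). In all, 3146 higher and 154 lower regions of 78989 passed (6902 and 3422 with a replicate block). The pIC count went from 3300 to 839 (without unstimulated replicate 2) to 2601 with 1 library left out, and 13 of 26 listed regions kept their call.

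CpG and Pam3CSK shared some of their largest gains. Regions near Spocd1 (chromosome 4, 129965587 to 129968462) rose by log2 4.72 ± 0.57 with CpG (9.55 ± 4.01 against 0.404 ± 0.274 CPM, adjusted p = 1.1e-04) and by log2 4.54 ± 0.58 with Pam3CSK (adjusted p = 2.2e-04). Ift88 (log2 4.06 ± 0.46 and 3.76 ± 0.47) and Il20rb (log2 3.93 ± 0.41 and 3.71 ± 0.42) regions rose with both. Peak1 (log2 3.98 ± 0.44) and Il6 (log2 2.82 ± 0.38) regions rose with CpG, and a Tmem131l region with Pam3CSK (log2 3.68 ± 0.45). Some inflammatory loci with the mark already present gained under both, among them Nfkbiz (log2 1.8 ± 0.18 and 1.68 ± 0.18), Nos2 (1.41 ± 0.13 and 1.27 ± 0.13) and Saa3 (1.23 ± 0.12 and 1.00 ± 0.12). Il1b followed (log2 1.02 ± 0.094 and 0.91 ± 0.095), and a Tulp2 region was lower with Pam3CSK (log2 -0.95 ± 0.13). CpG moved 2845 regions up and 140 down of 78989, and Pam3CSK 2105 up and 62 down. Fits without 1 library gave 939 (without unstimulated replicate 2) to 2445 for CpG, with 18 of 28 listed regions kept. They gave 611 (without unstimulated replicate 2) to 1951 for Pam3CSK, with 14 of 28 kept.

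With TNF the largest gains that held in every fit lay near Clptm1 (chromosome 7, 19634519 to 19637257; log2 3.70 ± 0.37, 11.2 ± 4.55 against 0.939 ± 0.533 CPM, adjusted p = 1.3e-04), Spint2 (log2 3.52 ± 0.35) and Il20rb (log2 3.48 ± 0.44). Regions at Nos2 (log2 1.36 ± 0.13, 39.4 against 15.5 CPM), Cxcl10 (log2 0.90 ± 0.11) and Ccl5 (log2 0.82 ± 0.12, 124 against 70.9 CPM) rose too. TNF moved the fewest regions of the 5 stimuli, 1030 higher and 5 lower of 78989, and 13 of 29 panel genes had a region that rose. The TNF count of 1035 became 121 (without unstimulated replicate 2) to 1004 with 1 library left out, and 6 of 23 listed regions kept their call. The Il15 region (log2 -1.05 ± 0.20) did not (adjusted p = 0.188 without unstimulated replicate 2).

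**Figure D1:**
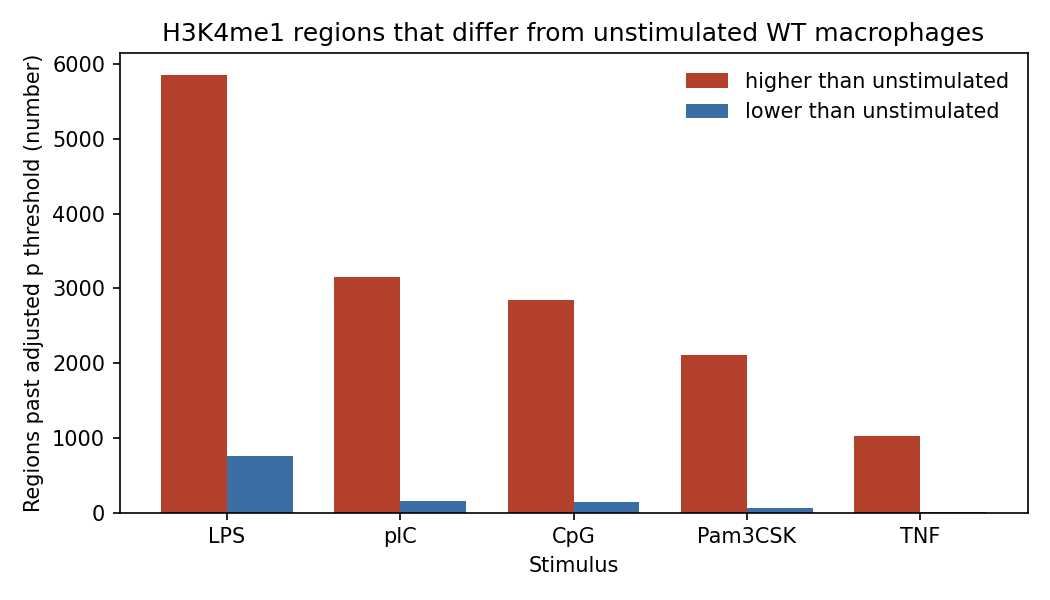
Numbers of H3K4me1 regions higher or lower than in unstimulated WT macrophages after each stimulus, past the adjusted p threshold, with 2 libraries per group.

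Direct comparison placed the Il6 region above its TNF level after LPS (5.64 ± 1.01 against 0.673 ± 0.212 CPM, log2 3.06 ± 0.35, adjusted p = 2.9e-04). Atp8a1 (chromosome 5, 67661823 to 67664546; log2 3.72 ± 0.51), Slco3a1 (3.56 ± 0.41), Ankrd29 (3.12 ± 0.37) and Fyb (3.07 ± 0.35) regions were also higher with LPS than with TNF. So were Tnfaip3 (log2 2.4 ± 0.32), Nos2 (1.71 ± 0.18) and Saa3 (1.09 ± 0.12) regions, while a Clptm1 region was lower (log2 -1.53 ± 0.29; adjusted p = 0.177 without TNF replicate 2). Against pIC, LPS raised regions near Lgals9 (chromosome 11, 78997380 to 78999447; log2 3.17 ± 0.33, 7.63 against 0.844 CPM), Clec16a (log2 2.95 ± 0.31) and Saa3 (log2 1.23 ± 0.12). LPS exceeded TNF at 1150 regions and fell short at 33 of 78989, and the same counts against pIC were 405 and 4. Left-out libraries changed 1183 to 237 (without TNF replicate 1) to 709 for LPS against TNF (8 of 16 listed regions kept). For LPS against pIC they changed 409 to 17 (without pIC replicate 2) to 274 (4 of 13 kept).

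CpG exceeded TNF near Tmed7 (chromosome 18, 46582760 to 46584836; log2 3.31 ± 0.31, 10.9 ± 0.916 against 1.09 ± 0.50 CPM, adjusted p = 3.2e-04), Clec16a (log2 2.93 ± 0.32), Dnajb6 (log2 2.85 ± 0.29) and Saa3 (log2 1.11 ± 0.12). For Pam3CSK against TNF the same loci led, Dnajb6 (log2 2.8 ± 0.29; adjusted p = 0.0712 without TNF replicate 2), Clec16a (log2 2.78 ± 0.32; adjusted p = 0.115 without TNF replicate 2) and Tmed7 (log2 2.75 ± 0.33; adjusted p = 0.15 without TNF replicate 2). Saa3 was higher as well (log2 0.88 ± 0.12; adjusted p = 0.205 without Pam3CSK replicate 2), and Klrg1 was lower (log2 -0.95 ± 0.17; adjusted p = 0.61 without TNF replicate 2). Of 78989 regions, 198 higher and 4 lower separated CpG from TNF and 60 higher and 1 lower separated Pam3CSK from TNF. Those counts became 10 (without TNF replicate 2) to 197 and 1 (without TNF replicate 2) to 57 when 1 library was left out. Of the listed regions, 4 of 15 kept the CpG call and 0 of 7 the Pam3CSK call.

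Regions that pIC but not Pam3CSK raised in WT cells gained little with pIC in dKO cells. The median log2 change with pIC was 0.41 in dKO, over the 2075 regions kept there by the filter on low counts (n = 1 library per stimulus). In WT it was 1.58 over all 2215. WT medians are edgeR log2 fold changes over the whole class and dKO medians log2 CPM differences over the regions kept. The gap between genotypes is therefore approximate. With LPS the median was 0.38 in dKO against 1.46 in WT. At the 1174 regions raised by Pam3CSK but not pIC, the medians with Pam3CSK were 1.01 in dKO against 1.17 in WT, and with CpG 0.92 in dKO against 1.18 in WT. LPS gave 1.12 in dKO against 1.10 in WT. The 927 regions of 931 raised by both stimuli kept a median of 1.05 (1.38) with Pam3CSK, 1.28 (1.66) with LPS and 0.59 (1.34) with pIC, WT in parentheses. TNF medians in the same order of classes were 0.69 (0.87), 0.43 (0.50) and 0.86 (1.13). For the 5697 regions raised by LPS the medians were 0.74 (1.37) with LPS, 0.38 (0.90) with pIC, 0.56 (0.86) with CpG, 0.57 (0.74) with Pam3CSK and 0.54 (0.64) with TNF. Remaining medians were 0.30 (0.68) with CpG and 0.26 (0.51) with Pam3CSK in the first class, 0.35 (0.47) with pIC in the next, and 1.02 (1.45) with CpG at regions raised by both. Every dKO median lay above all 10000 random region lists of equal size and signal. All share 1 unstimulated dKO library, whose spread the lists do not measure. WT values are inflated, as regions were chosen on those libraries, and 1 dKO library per stimulus allows no genotype test. The pIC and Pam3CSK sets shared 931 regions, against 83.8 for independent lists. In 5 simulations with no effect, and so no changed regions to share, the overlap was at most 1. They cannot show how much comes from shared unstimulated libraries.

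**Figure D2:**
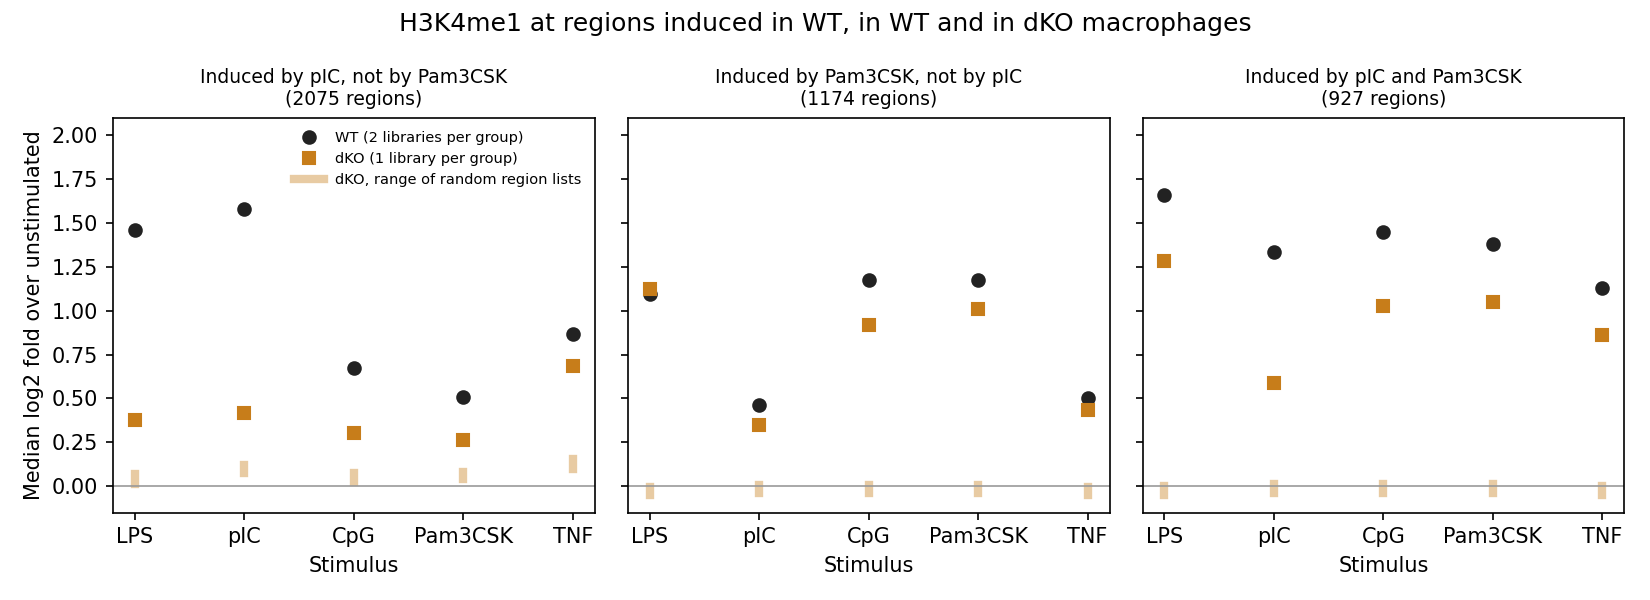
Median log2 change in H3K4me1 over unstimulated cells at 3 classes of WT-induced regions, in WT and in dKO macrophages. Bars mark the range of random region lists in dKO cells. WT and dKO measures differ, as given in the text.

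Before TNF, IkBaKO macrophages had less H3K4me1 at Nfkbia itself (chromosome 12, 55484224 to 55491519; 3.92 ± 0.173 against 39.5 ± 2.72 CPM, log2 -3.33 ± 0.15, adjusted p = 3.6e-16) and at a neighbouring Nfkbia region (log2 -2.32 ± 0.19). These cells lack the gene per the labels, and missing sequence and a lost mark were not told apart, since input libraries were not used here. The mark was also lower at Psmc1 (log2 -3.17 ± 0.21), Ryr2 (-2.50 ± 0.33), Rbms3 (-2.43 ± 0.28) and Marco (-1.27 ± 0.21; 3.34 against 8.17 CPM). It was higher near Fbxo8 (log2 3.75 ± 0.22, 10.3 against 0.758 CPM), Wdr27 (log2 3.72 ± 0.36) and Cd55b (log2 3.66 ± 0.19). Higher too were Cd55 (chromosome 1, 130425530 to 130440632; log2 3.27 ± 0.14, 48.9 against 5.04 CPM) and Il1b (log2 0.64 ± 0.11). The genotypes differed at 1846 higher and 1231 lower regions of 100055. With any 1 library left out 13 of 21 listed regions held, and the count of 3077 became 1040 (without IkBaKO 0 h replicate 4) to 1452.

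In Ctrl cells a region at Clptm1 gained H3K4me1 from 2 h of TNF on. Its CPM (chromosome 7, 19634305 to 19637536) went from 0.858 ± 0.0734 before TNF to 5.30 ± 0.351 at 2 h (log2 2.62 ± 0.26, adjusted p = 6.5e-07). It was 15.5 ± 1.12 at 8 h (log2 4.16 ± 0.21) and 8.35 ± 1.30 at 24 h (log2 3.30 ± 0.23). Nfkb1 (2.62 ± 0.31) and Alpk2 (2.25 ± 0.24) regions rose by 2 h, while the Nfkbia gene region fell (log2 -1.78 ± 0.14, 11.6 against 39.5 CPM). By 8 h regions at Rcl1 (log2 3.49 ± 0.29) and Il20rb (3.34 ± 0.32) had gained. Smaller gains lay at Nos2 (log2 1.30 ± 0.10, 32.4 against 13.2 CPM), Irf1 (0.94 ± 0.14), Nfkbiz (0.84 ± 0.12), Ccl5 (0.63 ± 0.074) and Cxcl10 (0.56 ± 0.097). At 24 h, a point the labels mark with a wash, regions at Dennd6a (log2 2.88 ± 0.28), Fscn1 (2.74 ± 0.29), Il20rb (2.74 ± 0.35) and Saa3 (1.14 ± 0.16) were above 0 h. Counts in Ctrl were 53 higher and 2 lower at 2 h, 1515 higher and 13 lower at 8 h and 1221 higher and 451 lower at 24 h, of 100055 tested. With each library left out in turn they became 11 (without Ctrl 2 h replicate 2) to 56, 677 (without Ctrl 0 h replicate 4) to 1346 and 199 (without Ctrl 24 h replicate 2) to 4066. Of the listed regions 5 of 9, 13 of 27 and 6 of 19 held.

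IkBaKO cells gained H3K4me1 at Clptm1 as well, 30.9 ± 0.235 CPM at 8 h against 1.48 ± 0.184 before TNF (log2 4.39 ± 0.17, adjusted p = 3.2e-18; log2 2.28 ± 0.21 at 2 h and 4.00 ± 0.18 at 24 h). A Gda region rose by 8 h (log2 3.77 ± 0.32, 6.57 against 0.467 CPM) and stayed up at 24 h (log2 3.54 ± 0.34). Fpr1 (log2 1.73 ± 0.26 and 1.87 ± 0.26), Irf1 (1.48 ± 0.13 and 0.94 ± 0.13) and Nos2 (1.28 ± 0.098 and 0.66 ± 0.10) regions followed. Kdm4a (log2 4.01 ± 0.40), Gbp2 (2.71 ± 0.43), Nfkbiz (1.22 ± 0.12) and Tnfaip3 (0.95 ± 0.12) regions were higher at 8 h. Cpeb4 (log2 -1.72 ± 0.29), Tgtp2 (-1.51 ± 0.18), Irf2 (-1.12 ± 0.19) and Ifit3 (-0.57 ± 0.10) regions were lower. The IkBaKO counts were 65 higher and 9 lower at 2 h, 3409 higher and 168 lower at 8 h and 3176 higher and 939 lower at 24 h of 100055. Without 1 library they were 11 (without IkBaKO 0 h replicate 2) to 32, 1915 (without IkBaKO 0 h replicate 4) to 2432 and 1339 (without IkBaKO 0 h replicate 4) to 2139. Listed regions kept their call in 1 of 11, 22 of 32 and 17 of 28 cases.

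More regions passed in IkBaKO than in Ctrl cells. By the interaction test in the main edgeR fit, however, the TNF response itself differed between the genotypes at 3 regions. At 2 h the Nfkbia gene region fell in Ctrl and not in IkBaKO cells (difference log2 1.88 ± 0.25, adjusted p = 0.00116). IkBaKO cells lack the gene per the labels and had little signal there before TNF. At 8 h the response at Traf2 (chromosome 2, 25531642 to 25537206; log2 -1.19 ± 0.17, adjusted p = 0.00776; adjusted p = 0.404 without Ctrl 8 h replicate 2) was lower in IkBaKO. So was that at Gpr55 (chromosome 1, 85984615 to 85989433; log2 -0.94 ± 0.15, adjusted p = 0.0209; adjusted p = 0.479 without Ctrl 8 h replicate 2). For 24 h edgeR found 0 regions of 100055, with 3808 under an unadjusted p of 0.05, and DESeq2 found 0 as well. At 8 h DESeq2 found 1 region higher and 4 lower. Left-out libraries gave 0 (without IkBaKO 2 h replicate 4) to 1 at 2 h and 0 (without Ctrl 0 h replicate 2) to 5 at 8 h. Tested on simulated data, 39% of 2-fold and 4% of 1.5-fold differences in response at 8 h were recovered, so differences of that size would mostly be missed. The same run called 7 unchanged regions, so single calls may be false as well.

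At later times another Cd55 region (chromosome 1, 130455178 to 130460910) was higher in IkBaKO. The log2 difference was 3.20 ± 0.21 at 2 h, 3.29 ± 0.20 at 8 h and 3.73 ± 0.21 at 24 h. Marco (log2 -1.17 ± 0.19 at 8 h, -1.11 ± 0.18 at 24 h) and Nfkbia (-1.98 ± 0.15 and -2.76 ± 0.15) stayed lower. At 8 h the Saa3 region stood at 26.5 ± 2.1 against 10.7 ± 0.813 CPM in Ctrl (log2 1.31 ± 0.13, adjusted p = 5.0e-08) and Irf1 was higher (log2 0.73 ± 0.12). Serpina3n (log2 -2.26 ± 0.17) and Relb (-2.1 ± 0.29) regions were lower. At 24 h Saa3 (log2 0.55 ± 0.084), Fpr1 (1.51 ± 0.27) and Nsun7 (2.86 ± 0.19) were higher. The genotypes differed at 1326 higher and 1065 lower regions at 2 h, 2845 higher and 1651 lower at 8 h and 2962 higher and 1726 lower at 24 h of 100055. These became 590 (without IkBaKO 2 h replicate 4) to 1083, 1202 (without IkBaKO 8 h replicate 4) to 2443 and 1111 (without Ctrl 24 h replicate 2) to 4748 without 1 library, with 11 of 16, 14 of 27 and 14 of 27 listed regions kept. From 8 h to 24 h, Ctrl cells lost H3K4me1 at Nos2 (log2 -0.76 ± 0.10, 18.9 against 32.4 CPM) and Sgpl1 (-1.26 ± 0.18), and IkBaKO cells regained it at Tgtp2 (log2 1.4 ± 0.18). In all 113 higher and 95 lower regions passed in Ctrl and 274 higher and 272 lower in IkBaKO. Those changes depended on single libraries, 14 (without Ctrl 24 h replicate 2) to 1171 in Ctrl and 8 (without IkBaKO 24 h replicate 4) to 119 in IkBaKO. Of the listed regions 2 of 13 and 1 of 18 kept their call.

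**Figure D3:**
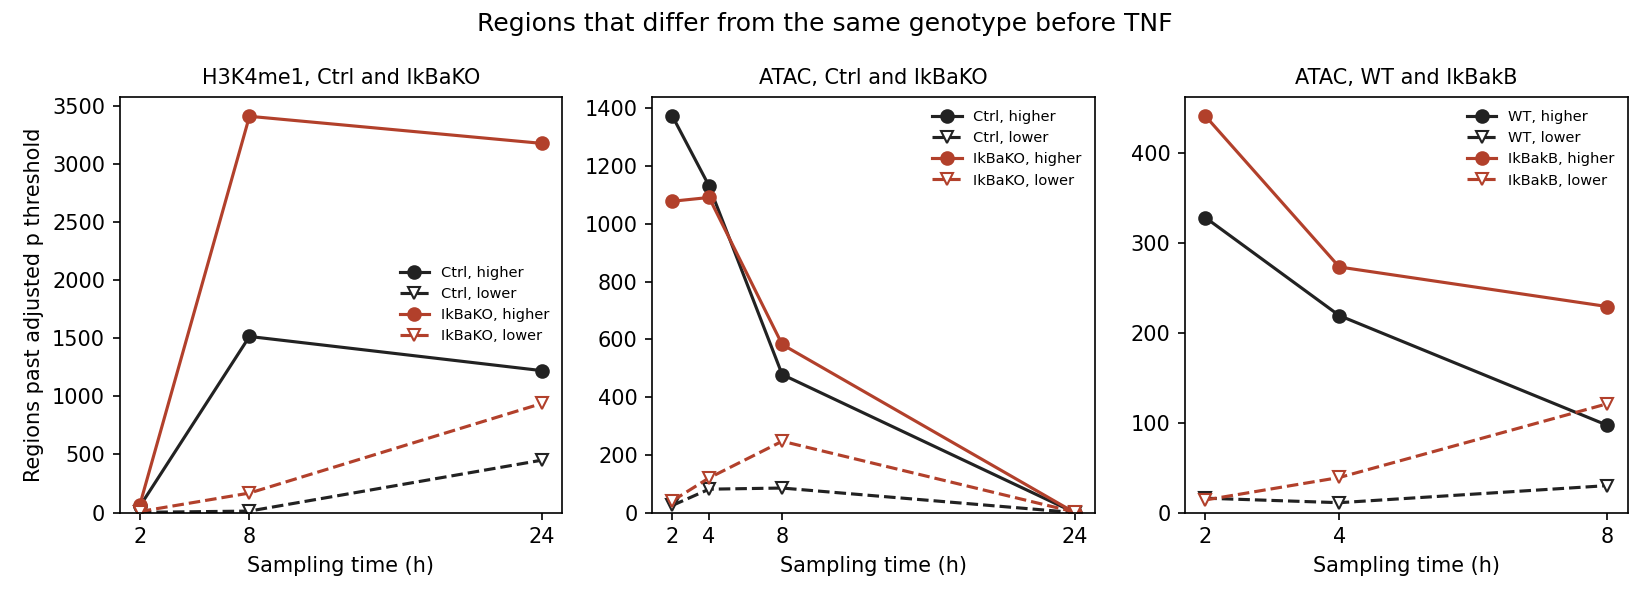
Numbers of H3K4me1 and ATAC regions higher or lower than in the same genotype before TNF, past the adjusted p threshold, by sampling time. The labels mark 24 h with a wash, and each group had 2 libraries.

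Chromatin opened in Ctrl cells at Nfkbiz (chromosome 16, 55838701 to 55838900) within 2 h of TNF (31.2 ± 3.96 against 5.85 ± 0.391 CPM, log2 2.39 ± 0.28, adjusted p = 2.6e-04) and was open at 4 h (log2 2.25 ± 0.28). Tnfaip3 (chromosome 10, 19009501 to 19009700; log2 2.08 ± 0.28 and 1.85 ± 0.28) and a window 46008 bp from Nfkbia (chromosome 12, 55443201 to 55443400; log2 3.28 ± 0.39 and 3.31 ± 0.38) did the same. An Adgrv1 window closed by 8 h (log2 -3.49 ± 0.49). Of 101681 overlapping windows, 1372 higher and 25 lower passed at 2 h, 1131 and 81 at 4 h, 478 and 85 at 8 h. Merging left 794, 662 and 305 separate higher sites. At 24 h edgeR found 0 windows (24 with a replicate block), with 5639 under an unadjusted p of 0.05, and DESeq2 found 0. Omitting single libraries gave 330 (without Ctrl 0 h replicate 3) to 716, 264 (without Ctrl 0 h replicate 3) to 614 and 36 (without Ctrl 0 h replicate 3) to 479. The call held for 3 of 24, 5 of 26 and 1 of 20 listed windows.

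IkBaKO cells opened windows near Hs1bp3 (chromosome 12, 8386801 to 8387000; 23.9 ± 1.46 against 0.328 ± 0.464 CPM, log2 5.67 ± 0.58, adjusted p = 2.0e-04 at 2 h; log2 5.85 ± 0.58 at 4 h). Il20rb (log2 5.98 ± 0.74 at 4 h, 16.5 against 0.164 CPM) and Nfkbiz (log2 1.93 ± 0.24 and 1.92 ± 0.25) windows opened too. At 8 h Isg15 was more open (log2 1.56 ± 0.25) and an Nrp1 window had closed (log2 -3.30 ± 0.42). Counts of 101681 windows were 1078 higher and 41 lower at 2 h and 1091 and 120 at 4 h. They were 582 and 247 at 8 h and 0 and 2 at 24 h. With a replicate block 24 h gave 255 and 238, so that count rests on the model. The 2 lay at Ago2 (log2 -2.72 ± 0.39, adjusted p = 0.0411). Removing 1 library changed them to 92 (without IkBaKO 0 h replicate 1) to 660, 116 (without IkBaKO 0 h replicate 1) to 640, 24 (without IkBaKO 0 h replicate 1) to 796 and 0 (without any one of the 4). Of the listed windows 4 of 21, 4 of 25, 2 of 23 and 0 of 2 kept their call.

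Between 8 h and 24 h windows closed at Acod1 in Ctrl cells (chromosome 14, 103056901 to 103057100; 0.131 ± 0.185 against 9.72 ± 0.124 CPM, log2 -5.73 ± 0.73, adjusted p = 4.4e-04). In IkBaKO cells the same was seen at Ccl5 (chromosome 11, 83530501 to 83530700; 1.07 ± 0.433 against 13.8 ± 6.51 CPM, log2 -3.66 ± 0.53). Tnfaip3 windows closed in both genotypes (log2 -2.02 ± 0.24 in Ctrl and -2.22 ± 0.36 in IkBaKO), as did Cxcl10 in Ctrl (log2 -1.44 ± 0.23). Nfkbiz (log2 -1.59 ± 0.21) and Ccdc88a (-4.56 ± 0.56) closed in IkBaKO, while a window at Hsf3 opened in both (4.49 ± 0.60 and 6.03 ± 0.69). Ctrl had 402 higher and 1119 lower of 101681 windows and IkBaKO 900 higher and 1278 lower. The counts fell to 214 (without Ctrl 24 h replicate 3) to 825 and 264 (without IkBaKO 8 h replicate 3) to 1914 in fits lacking 1 library, with 7 of 25 and 8 of 28 listed windows kept.

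ATAC counts at the Nfkbia gene were all but absent in IkBaKO cells, which lack it per the labels, 0.0961 ± 0.136 against 18.4 ± 1.92 CPM in Ctrl at 24 h (chromosome 12, 55491901 to 55492100; log2 -6.99 ± 0.48, adjusted p = 8.1e-06). At the earlier times the Nfkbia windows past the threshold had no counts in IkBaKO. Missing sequence and closed chromatin were not told apart here. A Pex16 window was higher at 24 h (log2 3.84 ± 0.39, 13.0 against 0.816 CPM). Few windows of 101681 separated the genotypes, those at Nfkbia included, 22 higher and 10 lower at 0 h, 5 higher and 11 lower at 2 h, 2 higher and 11 lower at 4 h, 2 higher and 13 lower at 8 h and 82 higher and 22 lower at 24 h. With touching or overlapping windows joined, the lower ones lay at 2 sites at each time up to 8 h and at 5 at 24 h. With 1 library omitted the first 3 became 0 (without IkBaKO 0 h replicate 1) to 11, 6 (without Ctrl 2 h replicate 1) to 10 and 0 (without IkBaKO 4 h replicate 1) to 7. Those at 8 h and 24 h became 7 (without IkBaKO 8 h replicate 1) to 11 and 25 (without Ctrl 24 h replicate 3) to 63. Of the listed windows 0 of 10, 5 of 10, 0 of 7, 5 of 7 and 7 of 11 kept their call. The interaction test found 0 windows with a different TNF response at 2, 4, 8 or 24 h (1815, 1717, 1733 and 1553 under an unadjusted p of 0.05). DESeq2 found 0 too. On simulated data 0% of 2-fold differences in response were recovered at 8 h, the time simulated, so the count there says little.

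In IkBakB cells the Nfkbia gene was less accessible than in WT at every time (chromosome 12, 55491747 to 55492983; 18.3 ± 2.4 against 90.0 ± 1.86 CPM at 0 h, log2 -2.30 ± 0.26, adjusted p = 3.7e-06). It stood at log2 -2.28 ± 0.23, -2.28 ± 0.22 and -2.04 ± 0.21 at 2, 4 and 8 h. The other lower regions lay mostly on the same chromosome, among them Eipr1 (chromosome 12, 28800297 to 28801136; log2 -4.10 ± 0.53, -2.89 ± 0.46, -2.97 ± 0.45 and -3.46 ± 0.42). Another was a region 189876 bp from Asap2 (log2 -4.47 ± 0.58, -2.81 ± 0.50, -3.51 ± 0.47 and -3.36 ± 0.44). Mid1 on chromosome X passed the threshold at 0 h alone (log2 -1.70, then -0.93, -1.06 and -0.92). Counts of 50505 regions were 0 higher and 6, 6, 7 and 8 lower at 0, 2, 4 and 8 h. They ran over 4 (without IkBakB 0 h replicate 1) to 7, 2 (without IkBakB 2 h replicate 2) to 4, 3 (without WT 4 h replicate 1) to 7 and 4 (without IkBakB 8 h replicate 2) to 6 with 1 library excluded. Of the listed regions 4 of 5, 2 of 6, 3 of 6 and 4 of 6 kept their call.

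**Figure D4:**
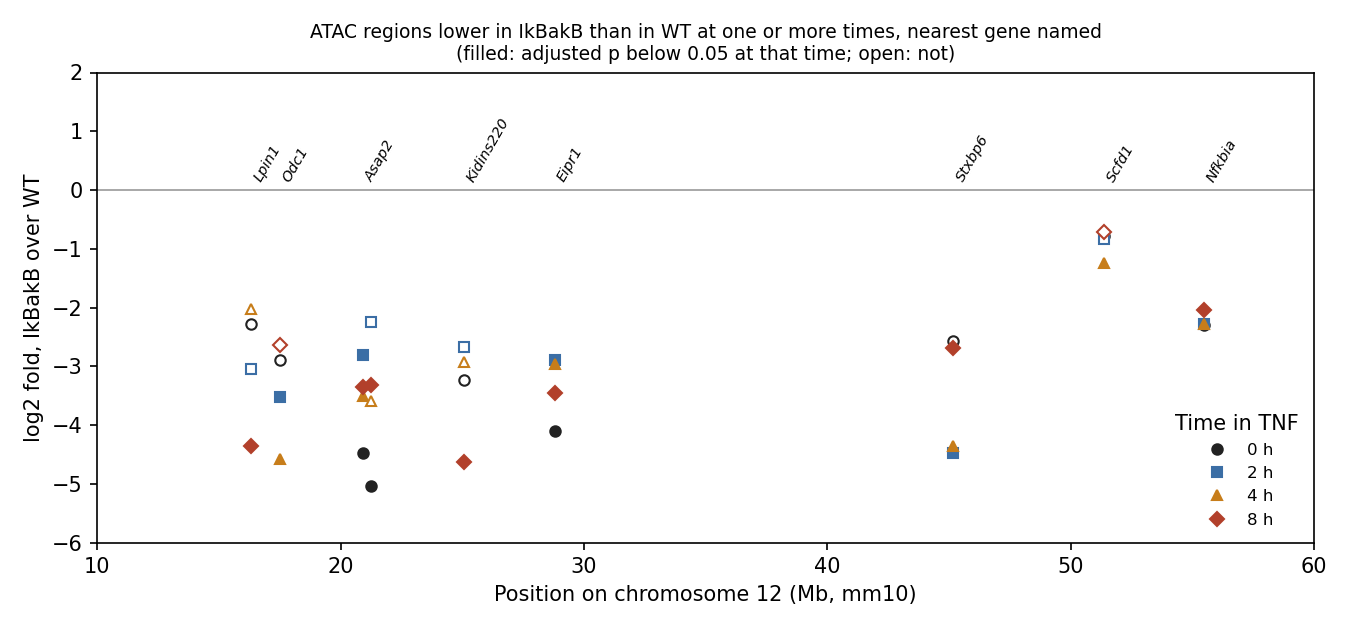
Log2 fold change, IkBakB over WT, of ATAC regions on chromosome 12 nearest a named gene that were lower in IkBakB at any time, by position. Filled markers passed the adjusted p threshold at that time and open markers did not.

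TNF opened an Nfkb1 region (chromosome 3, 135640199 to 135640543) in IkBakB cells by 2 h (18.2 ± 4.55 against 0.415 ± 0.586 CPM, log2 5.03 ± 0.75, adjusted p = 1.5e-04). Cxcl2 (log2 1.84 ± 0.27, 101 against 27.7 CPM) opened with it. WT cells opened Cxcl2 too (90.4 against 27.5 CPM, log2 1.73 ± 0.28; adjusted p = 0.13 without WT 0 h replicate 1). WT had 328 higher and 16 lower, 219 higher and 11 lower and 97 higher and 30 lower regions at 2, 4 and 8 h of 50505, and IkBakB 441 higher and 14 lower, 273 higher and 39 lower and 229 higher and 121 lower. Leave-one-out fits gave 11 (without WT 0 h replicate 1) to 190, 5 (without WT 0 h replicate 1) to 96 and 3 (without WT 0 h replicate 1) to 95 in WT, where 0 of 16, 0 of 17 and 0 of 12 listed regions kept their call. They gave 52 (without IkBakB 0 h replicate 1) to 182, 16 (without IkBakB 0 h replicate 1) to 138 and 4 (without IkBakB 0 h replicate 1) to 210 in IkBakB, where 4 of 17, 0 of 17 and 0 of 15 did. No region responded differently between IkBakB and WT by the interaction test in edgeR (0 at 2, 4 and 8 h; 1079, 1249 and 1117 under an unadjusted p of 0.05) or in DESeq2. Of simulated 2-fold differences in response at 8 h, 0% were recovered.

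RNA was read in Ctrl and IkBaKO cells before TNF (basal), at a point the labels mark as a wash, read here as the end of 8 h of TNF (called wash), and 1, 3 and 8 h later. What the cells were given after the wash is not given in the sources used here. The values at 1, 3 and 8 h are therefore not assigned to a further TNF response or to recovery from it. Nfkbia transcripts were nearly missing in IkBaKO libraries (0 to 7 counts per library) and plentiful in Ctrl (301 to 4676). Tnf (255 to 3508 counts in Ctrl, 247 to 6085 in IkBaKO), Rel (68 to 177 and 74 to 187) and Nfkbie (11 to 41 and 11 to 28) had counts in both genotypes, though the labels list all of them as deleted. Gene-level counts do not show whether the reads fall in the deleted part, so they do not check these deletions. Between genotypes these genes did not separate at any time, for example Tnf (log2 0.070 ± 0.57 basal, 0.021 ± 0.56 at wash, -0.038 ± 0.66 at 1 h with n = 1 in Ctrl, 0.90 ± 0.54 at 3 h and 0.49 ± 0.55 at 8 h). Other examples are Rel (log2 0.32 ± 0.20 basal and 0.33 ± 0.19 at 8 h) and Nfkbie (log2 -0.39 ± 0.42 and 0.11 ± 0.40).

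Without TNF, IkBaKO cells held Ifi202b (133 ± 17.8 against 0.104 ± 0.147 CPM, log2 10.56 ± 0.57, adjusted p = 1.7e-07), Cd55 (314 against 1.14 CPM, log2 8.50 ± 0.54) and Cd4 (2122 ± 125 against 79.4 ± 26.2 CPM, log2 4.75 ± 0.23) far above Ctrl. Slc39a4 (log2 5.13 ± 0.49), Mmp14 (4.12 ± 0.29), C3 (3.73 ± 0.42), Spic (3.33 ± 0.38), Ebi3 (1.05 ± 0.12) and Lyz2 (1.04 ± 0.13) were higher too. Nfkbia was at 0.851 against 67.9 CPM (log2 -6.58 ± 0.76). The NFkB pathway list leaned up (median log2 0.28, 6 higher and 0 lower of 28, 11 and 0 when adjusted over the list alone; adjusted p = 2.1e-06; adjusted p = 0.411 with an estimated correlation). Nfkb2 was among its calls (log2 1.21 ± 0.24; adjusted p = 0.148 without Ctrl basal replicate 2). The macrophage identity list leaned up too (median log2 0.24, 6 higher and 1 lower of 24, 9 and 2 when adjusted over the list alone; adjusted p = 9.8e-04; adjusted p = 0.349 with an estimated correlation). The cell cycle list leaned down (median log2 -0.57, 0 higher and 2 lower of 26, 0 and 22 when adjusted over the list alone; adjusted p = 3.3e-12; adjusted p = 0.394 with an estimated correlation). Of 11945 genes 256 higher and 200 lower passed. Scaling to total counts alone gave 182 and 412 and moved the median of all genes to -0.11 on the log2 scale. Without 1 library 43 (without Ctrl basal replicate 2) to 371 passed, and 10 of 46 listed genes held.

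At wash Ccl5 was higher in IkBaKO cells (346 ± 248 against 9.71 ± 0.899 CPM, log2 5.17 ± 0.61, adjusted p = 4.5e-04). Higher with it were Il1a (log2 2.08 ± 0.27), Ikbke (1.5 ± 0.20), Ifi202b (8.80 ± 0.48), Cd55 (7.40 ± 0.49), Cd4 (4.53 ± 0.23), C3 (3.27 ± 0.39) and Mmp14 (3.21 ± 0.24), while Cadm1 was lower (log2 -2.52 ± 0.32). List results were up for the NFkB pathway (median log2 0.36, 8 higher and 0 lower of 28, 12 and 0 when adjusted over the list alone; adjusted p = 6.5e-07; adjusted p = 0.371 with an estimated correlation). They were up for antimicrobial genes (median log2 0.65, 9 higher and 2 lower of 34, 14 and 3 when adjusted over the list alone; adjusted p = 3.5e-05; adjusted p = 0.3 with an estimated correlation) and down for the cell cycle (median log2 -0.73, 0 higher and 12 lower of 26, 0 and 24 when adjusted over the list alone; adjusted p = 2.1e-17; adjusted p = 0.296 with an estimated correlation). Stromal markers passed too (median log2 5.72, 0 higher and 0 lower of 12, 6 and 0 when adjusted over the list alone; adjusted p = 0.00251; adjusted p = 0.387 with an estimated correlation). Their sum was 301 CPM in IkBaKO wash replicate 2 and 14.2 CPM in replicate 1. The neutrophil markers Ngp and Ltf were near 0 in IkBaKO replicate 2 at every time, and how far this carries the antimicrobial list was not analysed here. Among 11945 genes 274 higher and 203 lower separated the genotypes at wash (215 and 331 by total counts). With 1 library left out the count was 45 (without Ctrl wash replicate 2) to 352, and 11 of 49 listed genes held. One hour later Ctrl had 1 library, so the spread in that comparison came from the other groups. Against that library, which cannot show whether it is typical of Ctrl, Mmp14 (log2 2.25 ± 0.30), Cd55 (6.61 ± 0.65) and Cd4 (4.30 ± 0.31) stood higher and Ptgs2 lower (-2.01 ± 0.23, 8.88 against 35.5 CPM). That comparison gave 36 higher and 14 lower genes (23 and 16 by total counts, 257 and 203 without the filter on low counts, 75 and 42 with DESeq2), or 15 (without IkBaKO 1 h replicate 2) to 23 with 1 IkBaKO library left out, and 8 of 22 listed genes kept their call.

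Vcam1 stood out at 3 h after the wash, 279 ± 47.6 against 44.1 ± 1.64 CPM in Ctrl (log2 2.66 ± 0.25, adjusted p = 9.4e-05). Also higher were Adgre4 (log2 3.14 ± 0.42), Il1a (1.87 ± 0.26, 63.7 against 17.3 CPM), Irak3 (1.30 ± 0.17), Birc2 (1.27 ± 0.16), Ebi3 (0.92 ± 0.11) and Wnt6 (2.56 ± 0.40). Ccl2 (log2 -1.14 ± 0.19, 251 against 553 CPM), Cxcl14 (-3.45 ± 0.45), Mmp13 (-2.41 ± 0.34), Angptl2 (-4.23 ± 0.66) and Hmga2 (-2.95 ± 0.39) were lower. The Ccl5 call was less secure (log2 2.48 ± 0.51; adjusted p = 0.134 without Ctrl 3 h replicate 2). The NFkB pathway list (median log2 0.70, 9 higher and 0 lower of 28, 15 and 0 when adjusted over the list alone; adjusted p = 4.8e-10; adjusted p = 0.37 with an estimated correlation) leaned up. The inflammatory cytokine list did too (median log2 0.57, 4 higher and 0 lower of 17, 6 and 1 when adjusted over the list alone; adjusted p = 0.00741; adjusted p = 0.165 with an estimated correlation). Cell cycle genes leaned down (median log2 -0.69, 0 higher and 12 lower of 26, 0 and 20 when adjusted over the list alone; adjusted p = 6.0e-12; adjusted p = 0.37 with an estimated correlation). At 3 h 449 higher and 357 lower genes of 11945 passed, or 318 and 588 by total counts, with an all-gene median of -0.099. Single left-out libraries gave 138 (without Ctrl 3 h replicate 2) to 677, with 20 of 61 listed genes kept.

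By 8 h after the wash the differences had widened in number. Vcam1 (218 ± 83.3 against 17.0 ± 3.90 CPM, log2 3.68 ± 0.27, adjusted p = 5.6e-06), Cxcl10 (175 against 13.7 CPM, log2 3.68 ± 0.52) and Ccl5 (774 against 118 CPM, log2 2.71 ± 0.51) were higher in IkBaKO. Icam1 (816 against 175 CPM, log2 2.22 ± 0.29) and Tlr2 (837 against 211 CPM, log2 1.99 ± 0.25) were as well. So were Rasgrp1 (log2 4.03 ± 0.58), Serpina3g (3.98 ± 0.51), Fscn1 (3.83 ± 0.64), Mmp9 (3.58 ± 0.44), Birc3 (1.66 ± 0.21), Sod2 (1.48 ± 0.20), Clec4e (1.90 ± 0.25), Nr1h3 (1.88 ± 0.18) and H2-K1 (0.92 ± 0.18). Mki67 (193 ± 8.97 against 447 ± 25 CPM, log2 -1.21 ± 0.17), Kif11 (-1.36 ± 0.16), Mcm2 (-1.06 ± 0.14), Cxcl14 (-3.78 ± 0.52), Hmga2 (-3.11 ± 0.39) and Itgb3 (-3.24 ± 0.51) were lower. The inflammatory cytokine list was higher whichever correlation was used (median log2 0.84, 5 higher and 0 lower of 17, 8 and 0 when adjusted over the list alone; adjusted p = 3.0e-04; adjusted p = 0.0432 with an estimated correlation). NFkB pathway genes also leaned up (median log2 0.91, 17 higher and 0 lower of 28, 19 and 0 when adjusted over the list alone; adjusted p = 6.8e-15; adjusted p = 0.117 with an estimated correlation). So did antigen presentation (median log2 0.79, 10 higher and 0 lower of 16, 15 and 0 when adjusted over the list alone; adjusted p = 5.9e-09; adjusted p = 0.117 with an estimated correlation) and interferon-stimulated genes (median log2 0.90, 6 higher and 0 lower of 44, 8 and 0 when adjusted over the list alone; adjusted p = 7.9e-08; adjusted p = 0.56 with an estimated correlation). The cell cycle list leaned down (median log2 -1.09, 0 higher and 23 lower of 26, 0 and 25 when adjusted over the list alone; adjusted p = 7.5e-21; adjusted p = 0.117 with an estimated correlation). The 8 h comparison gave 688 higher and 710 lower genes of 11945 (478 and 1083 by total counts, with an all-gene median of -0.13). Fits short of 1 library gave 454 (without IkBaKO 8 h replicate 2) to 1133, and 37 of 64 listed genes held.

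**Figure D5:**
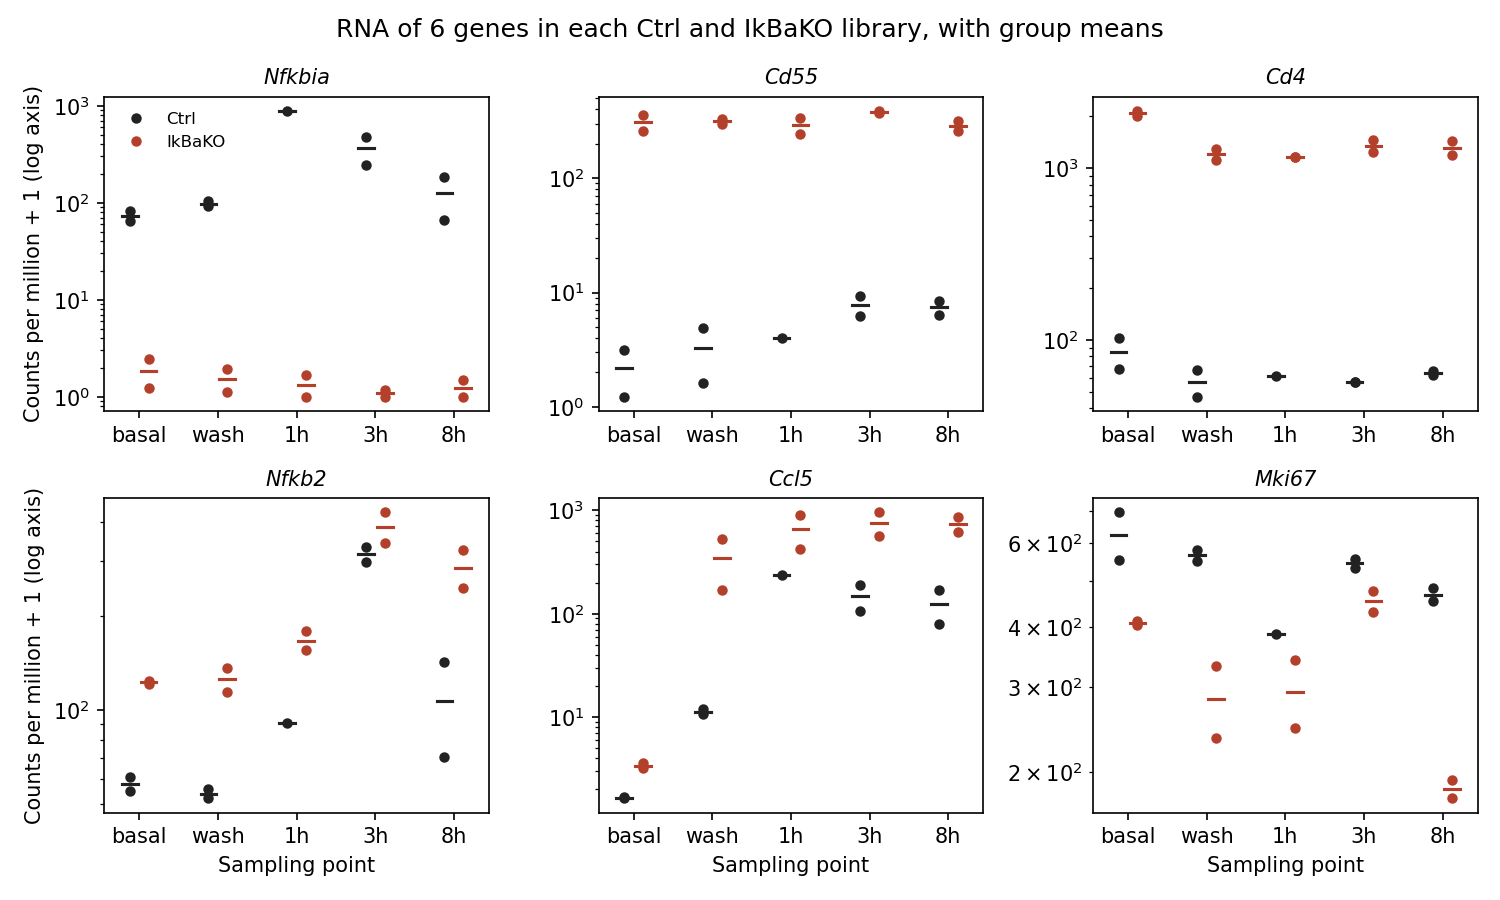
Library-scaled counts of Nfkbia, Cd55, Cd4, Nfkb2, Ccl5 and Mki67 in each Ctrl and IkBaKO library at the 5 sampling points. Short lines are group means, and the Ctrl group at 1 h has 1 library.

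In Ctrl cells Acod1 rose from wash to 3 h (1588 ± 67.1 against 22.8 ± 0.758 CPM, log2 6.12 ± 0.51, adjusted p = 1.5e-05). It rose with Icam1 (log2 3.43 ± 0.31), Cxcl10 (3.91 ± 0.57), Ccl5 (3.92 ± 0.60), Clec4e (3.70 ± 0.27), Tlr2 (3.03 ± 0.27) and Il1b (3.00 ± 0.44). Id1 (log2 -3.64 ± 0.61), Id3 (-3.23 ± 0.56) and Trib1 (-2.55 ± 0.30) fell. At 8 h Acod1 (log2 4.58 ± 0.48), Mmp14 (3.44 ± 0.24), Clec4e (2.99 ± 0.26) and Sod2 (1.83 ± 0.21) were above wash and Id3 below (-5.97 ± 0.74). Wash against basal gave Mmp14 (log2 2.32 ± 0.31, adjusted p = 0.013; adjusted p = 0.147 without Ctrl wash replicate 2). The NFkB pathway list (median log2 1.66, 20 higher and 0 lower of 28, 23 and 0 when adjusted over the list alone; adjusted p = 1.8e-25; adjusted p = 0.0477 with an estimated correlation) rose by 3 h under either correlation. The chemokine list (median log2 1.52, 7 higher and 0 lower of 21, 10 and 2 when adjusted over the list alone; adjusted p = 6.7e-07; adjusted p = 0.0144 with an estimated correlation) and the antimicrobial list (median log2 1.59, 16 higher and 0 lower of 34, 21 and 0 when adjusted over the list alone; adjusted p = 3.0e-18; adjusted p = 0.0146 with an estimated correlation) did as well. Ctrl counts of 11945 genes were 31 higher and 20 lower for wash against basal, 555 higher and 302 lower for 3 h (446 and 464 by total counts) and 95 higher and 49 lower for 8 h against wash. They became 0 (without Ctrl wash replicate 2) to 9, 291 (without Ctrl wash replicate 2) to 512 and 11 (without Ctrl wash replicate 2) to 144 without 1 library. Of the listed genes 0 of 20, 32 of 62 and 5 of 35 kept their call.

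IkBaKO cells raised Ccl5 from basal to wash (346 ± 248 against 2.45 ± 0.213 CPM, log2 7.11 ± 0.73, adjusted p = 7.2e-04) and Ccl9 (log2 1.33 ± 0.14). At 3 h Eno2 (log2 6.41 ± 0.96), Gem (5.79 ± 0.62), Rasgrp1 (5.55 ± 0.65), Acod1 (5.02 ± 0.47), Clec4e (4.60 ± 0.28), Gbp5 (3.64 ± 0.56), Il27 (3.62 ± 0.58) and Ptgs2 (2.71 ± 0.29) had risen. Dusp6 (log2 -3.59 ± 0.33), Id1 (-5.29 ± 0.87) and Ccl2 (-1.2 ± 0.19) had fallen. At 8 h Cxcl10 (log2 4.66 ± 0.57, 175 against 7.28 CPM), Clec4e (4.79 ± 0.29), Gbp5 (3.69 ± 0.56), Icam1 (2.53 ± 0.29) and Sod2 (2.63 ± 0.21) were above wash. Rrm2 (log2 -1.34 ± 0.21) and Kif11 (-0.98 ± 0.16) were below. The NFkB pathway list rose by 3 h (median log2 2.00, 25 higher and 0 lower of 28, 25 and 0 when adjusted over the list alone; adjusted p = 8.1e-24; adjusted p = 0.0568 with an estimated correlation). The interferon-stimulated list rose by 8 h (median log2 1.31, 22 higher and 0 lower of 44, 35 and 0 when adjusted over the list alone; adjusted p = 2.3e-14; adjusted p = 0.28 with an estimated correlation). IkBaKO counts of 11945 were 311 higher and 295 lower for wash against basal. They were 926 higher and 630 lower for 3 h (746 and 1065 by total counts, all-gene median -0.13 against -0.032) and 682 higher and 598 lower for 8 h (566 and 763). Lacking 1 library they were 6 (without IkBaKO basal replicate 2) to 526, 845 (without IkBaKO wash replicate 2) to 1305 and 251 (without IkBaKO 8 h replicate 2) to 1184, with 2 of 44, 51 of 70 and 27 of 66 listed genes kept.

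No gene's RNA response differed between IkBaKO and Ctrl by the interaction test in the main edgeR fit. A larger count in 1 genotype does not show a different response at Ccl5, Cxcl10 or another gene named here, nor is one excluded. The test gave 0 genes of 11945 for wash minus basal, 3 h minus wash and 8 h minus wash, with 264, 412 and 571 under an unadjusted p of 0.05. Without the filter edgeR gave 35, 93 and 158, and DESeq2 gave 0, 6 and 13. A replicate block gave 3 at 3 h and 3 at 8 h, and total counts 2 at 3 h. A left-out library raised the 3 h count to 2 (without IkBaKO 3 h replicate 1) and the 8 h count to 11 (without IkBaKO 8 h replicate 1), and 12% of simulated 2-fold differences were recovered for wash minus basal, the response simulated.

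Genes near the H3K4me1 regions whose 8 h response leaned most towards IkBaKO leaned higher in IkBaKO RNA at 3 h and 8 h after the wash with the preset correlation, and did not pass with an estimated one. No region had passed the interaction test in that direction, so the 200 with the smallest p and a positive difference were used. They have 183 nearest genes of which 128 were tested in RNA. Their median log2 difference was 0.19 at 3 h (16 higher and 4 lower; adjusted p = 0.00385; adjusted p = 0.0672 with an estimated correlation). It was 0.15 at 8 h (26 and 6; adjusted p = 0.00226; adjusted p = 0.0672 with an estimated correlation). Earlier medians were 0.058 basal, 0.063 at wash and 0.042 at 1 h (adjusted p = 0.533, 0.533 and 0.879; the mean at 1 h was -0.058). In the 131 ATAC windows that overlap a gained region, the median response difference was 0.17, 0.23, 0.27 and 0.074 at 2, 4, 8 and 24 h. The adjusted p was 0.021, 3.5e-04, 5.1e-04 and 0.659, or 0.643, 0.59, 0.59 and 0.897 with an estimated correlation. Windows can overlap each other, so 131 is not a number of separate gained regions. Over fits with 1 library left out these ran from -0.027 (without Ctrl 2 h replicate 1) to 0.38, 0.047 (without Ctrl 0 h replicate 3) to 0.47, 0.0063 (without IkBaKO 8 h replicate 3) to 0.43 and -0.12 (without IkBaKO 0 h replicate 1) to 0.26. Over the 174 regions of the WT data that overlap a gained region the median H3K4me1 leaned lower with Pam3CSK than with TNF (median log2 -0.13). No region passed the threshold, and the adjusted p of the set was 3.8e-04, or 0.374 with an estimated correlation. Left-out libraries moved it over -0.26 (without TNF replicate 1) to 0.051.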

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

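The RNA response differences at 3 h and 8 h, the tests of regions induced in WT cells, and the tests of NFκB activity across the genome, of T cells and of stromal transcripts were chosen only after the result was seen; the others in this part were set out before.

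Regions with a difference in TNF response between IkBaKO and Ctrl were Nfkbia, which IkBaKO cells lack per the labels, at 2 h (log2 1.88), Gpr55 (-0.94) and Traf2 (-1.19) at 8 h. The ATAC response at the gained H3K4me1 regions leaned to IkBaKO by a median log2 of 0.17 at 2 h, 0.23 at 4 h and 0.27 at 8 h with the preset correlation.

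RNA lists whose response differed between the genotypes with the preset correlation had these median differences in log2, IkBaKO minus Ctrl. From basal to wash: chemokines 0.23, antigen presentation 0.28, cell cycle -0.13, stromal markers 2.29. From wash to 3 h: chemokines -0.51, immediate early genes 0.29, cholesterol synthesis 0.22, stromal markers -2.70. From wash to 8 h: NFkB pathway 0.37, inflammatory cytokines 0.40, interferon-stimulated genes 0.74, immediate early genes 0.36, antigen presentation 0.50, glycolysis 0.27, cholesterol synthesis 0.41, cell cycle -0.33, stromal markers -2.40. None passed with an estimated correlation.

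Regions induced in WT cells also leaned in the IkBaKO minus Ctrl response with the preset correlation, by these medians in log2 of H3K4me1 at 8 h and 24 h: raised by pIC but not Pam3CSK 0.23 and 0.27, by both 0.15 and 0.17, by LPS 0.12 and 0.16, by TNF 0.19 and 0.21, higher with LPS than TNF 0.10 and 0.16, and at 24 h alone by Pam3CSK but not pIC 0.087 and higher with CpG than TNF 0.14. ATAC medians were -0.14 for both, -0.12 for TNF and -0.18 for Pam3CSK over TNF at 2 h, and 0.14 for pIC but not Pam3CSK at 24 h. These lists share the unstimulated libraries and many regions, and none passed with an estimated correlation.

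Of ATAC regions lower in IkBakB cells at any time, 90.9% (10 of 11) clustered on chromosome 12 at 16.3 to 55.5 Mb. That chromosome carries Nfkbia and 4.18% of regions tested. For altered NFκB activity acting across the genome, a bound of under 20% there was written only after that share had been seen. The bound is therefore no independent test. The share itself argues against such activity as the cause of all of these regions. Sequence variants linked to the allele predicted a surplus on chromosome 12 among lower regions that passed no test. Of these 15.3% lay there (17 of 111 with an unadjusted p under 0.01 at 0 h, ratio 3.67, Fisher exact p = 3.7e-06, 12 between the same positions), as predicted. Higher ones exceeded 4.18% too, at 8.16% (12 of 147). The lower ones share the 0 h libraries with those 11 and linked regions are not independent, so the Fisher p is no separate evidence. A linked stretch of another strain may account for these regions apart from the allele, and reads with variants were not used to test it.

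Genes that differed between IkBaKO and Ctrl RNA in one direction at basal, wash, 3 h and 8 h numbered 167 (116 higher, 51 lower; 163 with a position). If strain segments carried along with the genotype caused this, such genes could sit close together: 20.9% had another within 1 Mb, against a median of 23.9% and a 95th percentile of 31.3% in random lists. The value met the bound written beforehand for no such segments, but 7866 of 10000 random lists were at or above it, so it lies within their spread and decides nothing; that reading was settled after the value was seen. Cd4, one of these genes, did not come from T cells: Cd3e, Cd3d, Cd3g and Lck together reached at most 0.0454% of Cd4 in an IkBaKO library (0.676 CPM against a lowest Cd4 of 1099 CPM; in Ctrl 1.73 CPM and a highest Cd4 of 97.9 CPM).

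Stromal transcripts stood out in IkBaKO wash replicate 2, with 300.6 CPM summed over the list, 11.2 times the highest other library. That ratio prompted the question, so it decides nothing on RNA of stromal cells in that library, which stays open. An effect of the wash in IkBaKO cells is unlikely, since replicate 1 had 14.2 CPM, under the 19.9 CPM of the highest IkBaKO basal library. The stromal list values above, and genes shared with stromal cells at wash, rest on that library.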

How the results depend on the processing

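The alternatives for H3K4me1 and ATAC genotype at later times, 24 h against 8 h, and the RNA response differences at 3 h and 8 h, and leaving out libraries in the set tests, were chosen after seeing the data. Of 70 counts of calls, DESeq2 size factors kept all 70 within 1.5 times, total counts 66, no filter 58, the DESeq2 Wald test 27, and 137 of 330 values with 1 library left out stayed as near. Of 539 calls of named genes and 793 of named regions none turned direction anywhere; 528 and 504 stayed past the threshold with DESeq2, 536 and 787 with its size factors, 522 and 776 with total counts, 536 and 780 without the filter, and 1287 of 2110 and 1723 of 3184 with 1 library left out. The cause was not tested, except that left-out libraries leave fewer samples and the missing filter adds genes.

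Ngp had 0 to 3 counts in every IkBaKO RNA replicate 2 and 73 to 123 in every replicate 1, which unblocked fits count as spread. The labels do not tie same-numbered libraries to a shared culture or day. As a hint from the data and not the design, their deviations from the group means correlated above 0.1 in 15 of 15, 23 of 28, 45 of 45, 25 of 28 and 26 of 36 pairs of groups, at a median r of 0.287 in WT H3K4me1, 0.144 in Ctrl and IkBaKO H3K4me1, 0.32 and 0.183 in the 2 ATAC tables and 0.161 in RNA. With the number as a replicate block 13 counts stayed within 1.5 times and 57 grew, and no named call or set test changed; the unblocked count stands in parentheses, followed by the blocked higher and lower counts where their balance moved by over 10 percentage points. WT H3K4me1: LPS 15960 (6613; 10370 higher, 5590 lower), pIC 10324 (3300; 6902 higher, 3422 lower), CpG 9631 (2985; 6755 higher, 2876 lower), Pam3CSK 7961 (2167; 5840 higher, 2121 lower), TNF 4529 (1035; 3841 higher, 688 lower), LPS against TNF 6057 (1183; 4404 higher, 1653 lower), Pam3CSK against TNF 1703 (61; 1227 higher, 476 lower), CpG against TNF 2220 (202; 1720 higher, 500 lower), LPS against pIC 3167 (409; 2739 higher, 428 lower). Ctrl and IkBaKO H3K4me1: genotype at 0 h 6474 (3077), 2 h 4984 (2391), 8 h 8411 (4496), 24 h 9165 (4688), Ctrl 2 h 133 (55; 113 higher, 20 lower), 24 h 4932 (1672; 2646 higher, 2286 lower), 24 h against 8 h 1875 (208; 790 higher, 1085 lower), IkBaKO 2 h 201 (74), 8 h 5757 (3577; 4754 higher, 1003 lower), 24 h 9265 (4115; 5595 higher, 3670 lower), 24 h against 8 h 3056 (546), response difference 8 h 18 (2; 5 higher, 13 lower), 24 h 4 (0). Ctrl and IkBaKO ATAC: genotype at 0 h 89 (32; 73 higher, 16 lower), 2 h 48 (16; 26 higher, 22 lower), 4 h 34 (13; 17 higher, 17 lower), 8 h 68 (15; 42 higher, 26 lower), 24 h 466 (104), Ctrl 2 h 3311 (1397), 4 h 3365 (1212; 2703 higher, 662 lower), 8 h 2649 (563; 1912 higher, 737 lower), 24 h 24 (0), 24 h against 8 h 5085 (1521; 2080 higher, 3005 lower), IkBaKO 2 h 3209 (1119), 4 h 3944 (1211; 3005 higher, 939 lower), 8 h 3525 (829), 24 h 493 (2; 255 higher, 238 lower), 24 h against 8 h 8166 (2178). WT and IkBakB ATAC: genotype at 0 h 15 (6; 4 higher, 11 lower), 2 h 16 (6; 2 higher, 14 lower), 4 h 19 (7), 8 h 14 (8; 2 higher, 12 lower), WT 2 h 1058 (344), 4 h 788 (230; 656 higher, 132 lower), 8 h 777 (127; 464 higher, 313 lower), IkBakB 2 h 1321 (455; 1133 higher, 188 lower), 4 h 1256 (312; 891 higher, 365 lower), 8 h 1724 (350; 901 higher, 823 lower). RNA: genotype at basal 937 (456), wash 967 (477), 1 h 149 (50; 87 higher, 62 lower), 3 h 1340 (806), Ctrl wash against basal 155 (51), 3 h against wash 1304 (857), 8 h against wash 373 (144), IkBaKO wash against basal 1169 (606), response difference 3 h minus wash 3 (0), 8 h minus wash 3 (0).

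The DESeq2 Wald test moved 37 counts down and 6 up, edgeR in parentheses, with the DESeq2 higher and lower counts where their balance moved as far. WT H3K4me1: LPS 4103 (6613), pIC 1996 (3300), CpG 1952 (2985), LPS against TNF 711 (1183), LPS against pIC 260 (409). Ctrl and IkBaKO H3K4me1: genotype at 0 h 1256 (3077), 2 h 922 (2391), 8 h 1524 (4496), 24 h 1580 (4688), Ctrl 8 h 970 (1528), 24 h 650 (1672; 556 higher, 94 lower), 24 h against 8 h 78 (208), IkBaKO 2 h 47 (74), 8 h 2004 (3577), 24 h 1595 (4115), 24 h against 8 h 215 (546; 48 higher, 167 lower), response difference 8 h 5 (2; 1 higher, 4 lower). Ctrl and IkBaKO ATAC: genotype at 0 h 13 (32), 2 h 9 (16; 1 higher, 8 lower), 4 h 8 (13; 0 higher, 8 lower), 24 h 59 (104), Ctrl 2 h 746 (1397), 4 h 610 (1212), 8 h 166 (563), 24 h against 8 h 567 (1521; 71 higher, 496 lower), IkBaKO 2 h 496 (1119), 4 h 597 (1211), 8 h 244 (829), 24 h against 8 h 617 (2178; 143 higher, 474 lower). WT and IkBakB ATAC: genotype at 2 h 2 (6), 4 h 2 (7), 8 h 4 (8), WT 2 h 79 (344), 4 h 58 (230), 8 h 17 (127; 15 higher, 2 lower), IkBakB 2 h 97 (455), 4 h 70 (312; 69 higher, 1 lower), 8 h 38 (350; 29 higher, 9 lower). RNA: genotype at 1 h 117 (50), Ctrl wash against basal 140 (51), 8 h against wash 294 (144; 154 higher, 140 lower), response difference 3 h minus wash 6 (0), 8 h minus wash 13 (0).

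Without the filter on low counts 11 counts rose and 1 fell. WT and IkBakB ATAC: WT 8 h 76 (127). RNA: genotype at basal 1131 (456), wash 1240 (477), 1 h 460 (50; 257 higher, 203 lower), 3 h 1464 (806), Ctrl wash against basal 424 (51), 3 h against wash 1296 (857), 8 h against wash 699 (144), IkBaKO wash against basal 1197 (606), response difference wash minus basal 35 (0), 3 h minus wash 93 (0), 8 h minus wash 158 (0). Scaling to total counts moved 4 counts. Ctrl and IkBaKO H3K4me1: Ctrl 24 h against 8 h 339 (208), response difference 8 h 5 (2; 1 higher, 4 lower). Ctrl and IkBaKO ATAC: IkBaKO 24 h 1 (2). RNA: response difference 3 h minus wash 2 (0).

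Leaving out 1 library moved 193 values, 188 down and 5 up. Lowest and highest counts follow. WT H3K4me1: CpG 939 to 2445, CpG against TNF 10 to 197, LPS 2691 to 4979, LPS against TNF 237 to 709, LPS against pIC 17 to 274, pIC 839 to 2601, Pam3CSK 611 to 1951, TNF 121 to 1004, Pam3CSK against TNF 1 to 57. Ctrl and IkBaKO H3K4me1: genotype at 0 h 1040 to 1452, 2 h 590 to 1083, 8 h 1202 to 2443, 24 h 1111 to 4748, Ctrl 2 h 11 to 56, 8 h 677 to 1346, 24 h 199 to 4066, 24 h against 8 h 14 to 1171, IkBaKO 2 h 11 to 32, 8 h 1915 to 2432, 24 h 1339 to 2139, 24 h against 8 h 8 to 119, response difference 2 h 0 to 1, 8 h 0 to 5. Ctrl and IkBaKO ATAC: genotype at 0 h 0 to 11, 2 h 6 to 10, 4 h 0 to 7, 8 h 7 to 11, 24 h 25 to 63, Ctrl 2 h 330 to 716, 4 h 264 to 614, 8 h 36 to 479, 24 h against 8 h 214 to 825, IkBaKO 2 h 92 to 660, 4 h 116 to 640, 8 h 24 to 796, 24 h 0 to 0, 24 h against 8 h 264 to 1914. WT and IkBakB ATAC: genotype at 2 h 2 to 4, 4 h 3 to 7, 8 h 4 to 6, WT 2 h 11 to 190, 4 h 5 to 96, 8 h 3 to 95, IkBakB 2 h 52 to 182, 4 h 16 to 138, 8 h 4 to 210. RNA: genotype at basal 43 to 371, wash 45 to 352, 1 h 15 to 23, 3 h 138 to 677, 8 h 454 to 1133, Ctrl wash against basal 0 to 9, 3 h against wash 291 to 512, 8 h against wash 11 to 144, IkBaKO wash against basal 6 to 526, 3 h against wash 845 to 1305, 8 h against wash 251 to 1184, response difference 3 h minus wash 0 to 2, 8 h minus wash 0 to 11.

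With an estimated correlation 1 of 33 RNA list calls between genotypes was left and total counts gave 37; the set tests of Pam3CSK against TNF (median -0.13) and of the ATAC response at 2, 4 and 8 h (0.17, 0.23 and 0.27) no longer passed, nor did those of RNA near gained regions at 3 h and 8 h once adjusted (adjusted p = 0.0672 for both). Leaving out 1 library ran the first from -0.26 to 0.051 and the ATAC medians from -0.027 to 0.38, 0.047 to 0.47, 0.0063 to 0.43 and -0.12 to 0.26 at 24 h, reversing 7 of 54 values. Total counts reversed the RNA medians near gained regions at basal (-0.051), wash (-0.024) and 1 h (-0.011). Other region overlaps, nearest genes within 25 kb and 200 regions of either direction changed no set test.

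The dKO medians stayed positive everywhere. They left the width of the random lists with total counts (at regions raised by pIC but not Pam3CSK pIC 0.48, TNF 0.77, by Pam3CSK but not pIC pIC 0.41, TNF 0.52, by both pIC 0.66, TNF 0.95, by LPS pIC 0.44, CpG 0.59, Pam3CSK 0.60, TNF 0.63), with a prior count of 0.5 (by LPS LPS 0.77, CpG 0.59, Pam3CSK 0.60, TNF 0.58) and with WT sets of at least 2-fold (at regions raised by pIC but not Pam3CSK pIC 0.57, CpG 0.36, TNF 0.89, by Pam3CSK but not pIC LPS 1.53, pIC 0.56, CpG 1.24, Pam3CSK 1.34, TNF 0.73, by both LPS 1.71, pIC 0.88, CpG 1.36, Pam3CSK 1.39, TNF 1.25, by LPS LPS 0.98, pIC 0.57, CpG 0.75, Pam3CSK 0.76, TNF 0.81). The motif test and its alternatives were not run, and the dKO libraries allow no block or left-out library.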

Other observations

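Lists not described so far were compared between IkBaKO and Ctrl as well. At 8 h after the wash those that did not pass were chemokines (median log2 0.12, 4 higher and 1 lower of 21, adjusted p = 0.28), immediate early genes (median log2 0.18, 2 higher and 1 lower of 24, adjusted p = 0.95), alternative activation (median log2 0.30, 0 higher and 1 lower of 13, adjusted p = 0.647), glycolysis and hypoxia (median log2 0.096, 2 higher and 1 lower of 19, adjusted p = 0.531), cholesterol and lipid synthesis (median log2 0.14, 2 higher and 0 lower of 20, adjusted p = 0.192), survival and apoptosis (median log2 0.19, 3 higher and 1 lower of 26, adjusted p = 0.0534), genotype genes (median log2 0.22, 0 higher and 1 lower of 4, adjusted p = 0.647), neutrophil markers (median log2 -0.28, 1 higher and 0 lower of 10, adjusted p = 0.939), dendritic cell markers (median log2 -0.12, 1 higher and 0 lower of 7, adjusted p = 0.647), lymphocyte markers (median log2 0.19, 1 higher and 0 lower of 3, adjusted p = 0.157), osteoclast markers (median log2 -0.041, 0 higher and 0 lower of 5, adjusted p = 0.95), stromal markers (median log2 1.39, 0 higher and 0 lower of 12, adjusted p = 0.834). Antimicrobial genes at 8 h had a median log2 of 1.11 (15 higher and 2 lower of 34, adjusted p = 6.0e-07; adjusted p = 0.117 with an estimated correlation), and macrophage identity genes 0.28 (7 higher and 0 lower of 24, adjusted p = 0.00201; adjusted p = 0.117 with an estimated correlation).

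Before TNF the immediate early list was lower (median log2 -0.33, 0 higher and 2 lower of 24, adjusted p = 0.0104; adjusted p = 0.411 with an estimated correlation) and the antimicrobial list higher (median log2 0.35, 4 higher and 1 lower of 34, adjusted p = 0.0178; adjusted p = 0.411 with an estimated correlation), while interferon-stimulated genes did not differ (median log2 -0.27, 0 higher and 0 lower of 44, adjusted p = 0.58). At wash antigen presentation leaned up (median log2 0.41, 3 higher and 0 lower of 16, adjusted p = 0.00198; adjusted p = 0.387 with an estimated correlation) and glycolysis (median log2 -0.27, 0 higher and 1 lower of 19, adjusted p = 0.0253; adjusted p = 0.507 with an estimated correlation) and cholesterol synthesis (median log2 -0.36, 1 higher and 0 lower of 20, adjusted p = 0.0424; adjusted p = 0.632 with an estimated correlation) down. Chemokines at wash had a median of -0.24 and a mean of 0.46 (adjusted p = 0.636). Over time in Ctrl, cholesterol synthesis leaned down from basal to wash with the preset correlation, with no member past the threshold (median log2 -0.59, 0 higher and 0 lower of 20, adjusted p = 9.8e-06; adjusted p = 0.546 with an estimated correlation; 10 of 20 lower when adjusted over the list alone) and antimicrobial genes were higher at 8 h than at wash (median log2 1.31, 8 higher and 0 lower of 34, adjusted p = 1.9e-15; adjusted p = 0.0473 with an estimated correlation); in IkBaKO, chemokines rose from basal to wash (median log2 0.95, 5 higher and 0 lower of 21, adjusted p = 3.3e-06; adjusted p = 0.0193 with an estimated correlation) and cell cycle genes fell by 8 h (median log2 -0.62, 0 higher and 14 lower of 26, adjusted p = 2.1e-10; adjusted p = 0.229 with an estimated correlation).

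Several classes of regions raised in WT cells also leaned to the mutant before TNF. Each class is given by its WT stimulus with its median log2 difference at 0 h, the adjusted p with the preset correlation, and then the adjusted p with an estimated correlation, under which none passed. IkBaKO against Ctrl, ATAC: Pam3CSK but not pIC 0.12 (adjusted p = 3.6e-05; 0.168), both 0.34 (adjusted p = 9.6e-14; 0.168), LPS 0.11 (adjusted p = 2.8e-04; 0.41), TNF 0.33 (adjusted p = 5.6e-14; 0.168), Pam3CSK over TNF 0.29 (adjusted p = 0.00299; 0.266). IkBaKO against Ctrl, H3K4me1: Pam3CSK but not pIC 0.15 (adjusted p = 1.7e-06; 0.411), both 0.20 (adjusted p = 1.6e-09; 0.463), TNF 0.19 (adjusted p = 1.1e-09; 0.416), Pam3CSK over TNF 0.16 (adjusted p = 7.3e-04; 0.411), CpG over TNF 0.098 (adjusted p = 0.0296; 0.635). IkBakB against WT, ATAC: pIC but not Pam3CSK 0.28 (adjusted p = 9.7e-07; 0.411), Pam3CSK but not pIC 0.12 (adjusted p = 0.0362; 0.411), both 0.15 (adjusted p = 0.00445; 0.523), LPS 0.16 (adjusted p = 0.00174; 0.411), TNF 0.21 (adjusted p = 4.9e-04; 0.411), LPS over TNF 0.17 (adjusted p = 0.0115; 0.411), CpG over TNF 0.21 (adjusted p = 0.0362; 0.266). No class differed in response between IkBakB and WT.

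Markers of other cells varied between libraries. Neutrophil transcripts summed to 43.8 to 107 CPM in IkBaKO replicate 2, 169 to 232 in its replicate 1 and 108 to 167 in Ctrl; Ngp had 0 to 3 counts, 73 to 123 and 48 to 211 in the same order, and Ltf 0 to 2 in IkBaKO replicate 2. Erythroid and mast cell transcripts summed to 0 to 30 counts per library, and too few members passed the filter for a test of that list.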
